A study of Caenorhabditis elegans with 2 samples.

How the data were processed

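The assay was chromatin immunoprecipitation followed by sequencing (ChIP-seq) on Caenorhabditis elegans late embryos, collected 5 hours after synchronization by bleaching, per the labels. The worms carried a transgene that fuses the protein C08G9.2 to GFP, and an antibody against GFP was used for the precipitation, per the labels. The labels place both samples in 1 group and number them as 2 biological replicates. A control library was used upstream, per the deposited text records, and was not analysed here. No comparison with untagged worms was made.

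The authors deposited peak lists, not reads. For each of 2 genome builds, ce10 and ce11, there were 4 lists. Of these, 3 held regions called in replicate 1, in replicate 2 and in both replicates pooled. The last was a thresholded list made from these 3 by irreproducible discovery rate (IDR), a method based on how alike replicates rank regions. Single peaks in the thresholded list can still rank far apart in the 2 replicates. The per-replicate and pooled lists were described in the deposited records as peaks together with background, so they hold weak regions by design. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here. Each region carries a signal value as the authors deposited it. The scale of that signal is not stated, so it served only to describe, rank or filter regions within a list. The deposited lists also hold a −log10 q-value per region, which was used in no test, and the offset of the summit from the region start. The lists give no read counts, so the sequencing depth of both replicates is unknown and no depth-based interval could be given. Intervals on shares are 95% exact Clopper-Pearson intervals and treat peaks or genes as independent, which neighbouring ones need not be.

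The ce11 lists were used for every result that needs sequence or annotation, with the WBcel235 genome (the same assembly as ce11) and Ensembl release 115 gene models. None of the ce11 regions ran past a chromosome end (0 regions), and 0 regions of any list lay outside the 6 nuclear chromosomes. The ce10 lists were compared by counts and signal ranks alone. Coordinates are 1-based on ce11. A gene start is the 5′ end of the gene record.

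Thresholded peaks were compared with background regions, defined as the pooled regions that overlap no thresholded peak by at least 1 bp (28206 regions). All 1416 thresholded peaks were the 1416 pooled regions of highest signal, so each such comparison sets high-signal against lower-signal regions of the same reads. A promoter peak has its summit within 500 bp of a protein-coding gene start. Classes were assigned in the order promoter, 5′ UTR, coding exon, 3′ UTR, intron, non-coding gene, downstream and intergenic. Shares were tested with two-sided Fisher exact tests and adjusted by the Benjamini-Hochberg method within each family (8 classes, 6 chromosomes, 10 non-coding biotypes with at least 20 genes, 41 gene lists, or all 7-mers) at 0.05. A gene list was tested against all other protein-coding genes, of which 19973 were used in all. 7-mers, counted on both strands, were tested in 101 bp windows at summits against windows of the same length centred 500 bp to either side. GC content was compared by a permutation test with 100000 resamples. Replicate overlap was set against 100 permutations of the ranks of the replicate 2 list.

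The gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes C08G9.2 and unc-119, the genes at the 25 peaks of highest signal (starts within 500 bp of the summit, otherwise the nearest protein-coding start), and from each gene list past the threshold up to 6 members with a peak, highest signal first, or up to 2 from other lists. Non-coding RNA genes outside that rule were chosen after their values were seen. Alternatives covered the peak set, the background, window sizes, k, the overlap rule, the build and leaving out each replicate, which meant taking the 1416 highest-signal regions of the other replicate's list and its own remaining regions as background. GC-matched background took 1 background window per peak with nearly the same number of G and C bases. Gene lists were also tested across 5 strata of GC content within 250 bp of the gene start by the Mantel-Haenszel method. The gene-list and 7-mer tests were first run on simulated data. With 25% of planted list genes bound against 4% of others, 93% of 100 planted lists were recovered and 3 of 661 unplanted lists passed. The planted lists held at least 25 genes, so smaller lists, weaker enrichment and depletion were not covered. With 7-mers planted in 6% of windows, 97.5% of 200 were recovered and 0 of 8192 passed without planting. Those windows lay beside the summits, so both sides were flank sequence and calls due to the base composition of summits were not covered. Calculations used Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.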

Results

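C08G9.2 is annotated as an uncharacterized protein of the nematode Caenorhabditis elegans. Its GFP fusion was precipitated from whole late embryos, and the places in the genome recovered with it were recorded as peak lists. There was 1 group with 2 biological replicates and no second condition, so the questions the design allows are where the protein was recovered, how alike the replicates were, and which genes lay at the peaks. Depth is unknown because the lists hold no read counts.

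The tagged gene and the marker gene named in the strain label were examined first. No thresholded peak lay over C08G9.2 (WBGene00015620, chromosome IV, 7664157 to 7672972, minus strand). Its best pooled region ranked 6741 of 30000, with a signal of 53.5, and its best regions ranked 3089 of 27783 in replicate 1 and 14393 of 29382 in replicate 2. No thresholded peak lay over unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935, plus strand), where the best pooled region ranked 3273 with a signal of 70.3.

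The thresholded list held 1416 peaks on ce11, which covered 528581 bases or 0.527% of the nuclear genome. Their signal ran from 96.98 to 2395, with a median of 135, and 55 peaks exceeded 500. The peak of highest signal lay on chromosome III (8043743 to 8044205), in intergenic sequence 527 bp upstream of the start of K12H4.5. The next (chromosome III, 3499810 to 3500272, signal 1429) lay in an intron of M01F1.8, with M01F1.9 the nearest start. The third (chromosome I, 5807227 to 5807671, signal 976) lay between lin-35, which encodes the worm retinoblastoma-related protein, and vps-51, and the fourth (chromosome IV, 3050444 to 3050873, signal 976) was intergenic, 555 bp upstream of eel-1, a ubiquitin ligase gene. Of the 25 peaks of highest signal, 16 were in promoters, 5 in introns and 4 in intergenic sequence. The promoter peaks included K10D2.5, a peak at the starts of cux-7 and C07H6.2, nrde-4 (nuclear RNA interference), jmjd-1.2 (a histone demethylase) with F29B9.11, chaf-2 (a chromatin assembly factor subunit) with Y71G12B.30, thoc-5 (mRNA export), bag-1 (a co-chaperone) and pinn-1 (a prolyl isomerase). The nrde-4 peak (chromosome IV, 7654435 to 7654734, signal 849) lay 9423 bp from the C08G9.2 gene body, and a weaker peak (7658611 to 7659040, signal 148, rank 621) lay 5117 bp from it. A pair of the intronic peaks lay at snoRNA genes, T03F7.8 in cutl-18 and C51F7.3 with C51F7.4 in frm-7.

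The replicates shared most of their highest-ranked regions. Of the 1416 highest-signal regions of replicate 1, 982 (69.4%) overlapped one of the 1416 highest-signal regions of replicate 2, against a mean of 6.15% and a maximum of 7.49% when ranks were permuted (one-sided permutation p = 0.01, the smallest that 100 permutations can give). This p compares these libraries and treats regions as independent. Among the 25 peaks of highest signal the worst rank was 60 in replicate 1 and 38 in replicate 2. Across the 1415 thresholded peaks found in both lists, Spearman's rho of signal was 0.734. These peaks, like the 25 above, are those of highest pooled signal, which draws on both replicates. Spearman's rho was 0.444 across the 16690 regions of replicate 1 (60.1% of its list) that matched a region of replicate 2. Both values are across regions, which are not independent replicates.

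**Figure D1:**
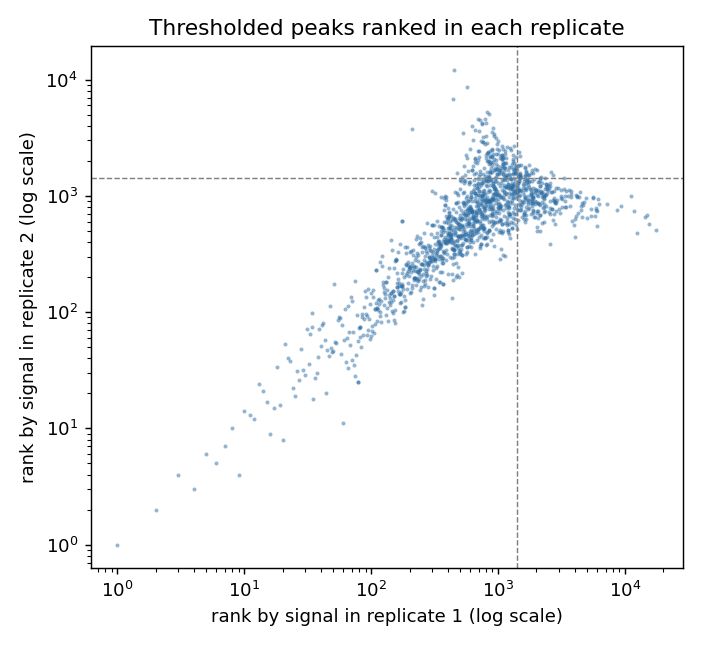
Rank by signal of each thresholded peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), 1 point per peak found in both lists (1415 peaks), with dashed lines at rank 1416. The 25 peaks of highest signal rank within 60 in replicate 1 and within 38 in replicate 2, and 976 of the peaks overlap a region inside the dashed lines in both replicates.

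Peaks lay at promoters more often than background regions did. A summit within 500 bp of a protein-coding gene start was found for 657 of 1416 peaks (46.4%, 95% interval 43.8 to 49.0) and for 21.3% of background regions (odds ratio 3.20, Fisher exact p = 3.57e-92). These summits lay mostly upstream, 577 of 657, at a median of 159 bp before the start. Coding exons held 4.80% of peaks (3.75 to 6.05) against 25.5% of background regions (odds ratio 0.147, exact adjusted p = 9.53e-92) and 1.13% of the 708 peaks of highest signal (odds ratio 0.0334). The 3′ UTRs held 0.494% against 2.45% (exact adjusted p = 5.51e-08). Introns held 20.4% against 25.9% (exact adjusted p = 4.48e-06) and non-coding genes 7.27% against 3.43% (exact adjusted p = 3.83e-11). Each summit counts in 1 class and promoters come first, so the larger promoter share leaves less for later classes. Outside promoters, introns held 289 of 759 peaks and 7300 of 22196 background regions, a larger share of the peaks. Coding exons held 68 and 7196 of these, still a smaller share of the peaks. These comparisons outside promoters were not tested, so the intron result does not show that peaks avoid introns. The shares in 5′ UTRs, downstream sequence and intergenic sequence did not pass the adjusted threshold. The intergenic share was above background and passed with a 250 bp window (27.3% of peaks, exact adjusted p = 1.2e-06). It was below background and passed with a 1000 bp window (9.82%, exact adjusted p = 0.000823), among the 708 peaks of highest signal (13.0%, exact adjusted p = 0.00326) and against random positions (exact adjusted p = 1.62e-07). The downstream share was above background and passed with a 250 bp window (3.53%, exact adjusted p = 4.76e-05), among the 708 peaks of highest signal (4.94%, exact adjusted p = 0.00634) and without replicate 2 (3.95%, exact adjusted p = 0.0242).

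**Figure D2:**
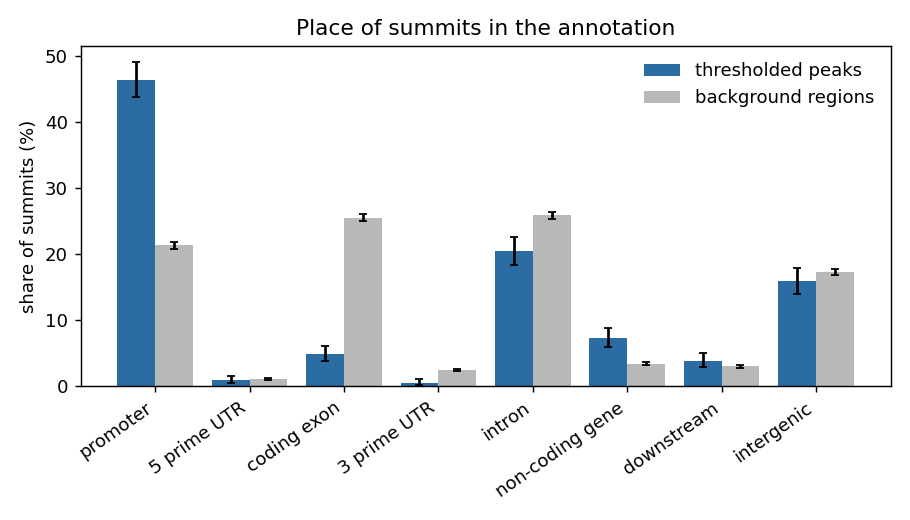
Share of summits (y axis, percent) in each annotation class (x axis) for 1416 thresholded peaks and 28206 background regions, with 95% Clopper-Pearson intervals as error bars. Promoters hold 46.4% of peaks and 21.3% of background regions, and coding exons 4.80% and 25.5%.

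Transfer RNA genes stood out among non-coding genes. A tRNA gene start lay within 500 bp of 167 peaks (11.8%, 10.2 to 13.6) against 0.833% of background regions (odds ratio 15.9, exact adjusted p = 8.73e-112), and 184 of 612 tRNA genes (30.1%) had such a peak. Their summits lay at a median of 15 bp after the tRNA gene start, with quartiles of 5 bp before and 44 bp after, and 50 of the 167 (29.9%) lay upstream of it. Small nucleolar RNA genes, which guide RNA modification, were near 67 peaks (4.73% against 0.574%, odds ratio 8.60, exact adjusted p = 1.05e-33), and microRNA genes near 24 peaks (1.69% against 0.308%, odds ratio 5.57, exact adjusted p = 1.03e-09). Small nuclear RNA genes were near 13 peaks (odds ratio 6.69, exact adjusted p = 1.43e-06), genes of the broad annotated class ncRNA near 351 (odds ratio 3.1, exact adjusted p = 4.78e-57), and antisense RNA genes near 6 (odds ratio 5.00, exact adjusted p = 0.00435). The antisense result did not pass with a 250 bp window (odds ratio 1.53, exact adjusted p = 0.709) or against the smaller GC-matched background (6 of 1416 peaks against 0 of 1416 windows, exact adjusted p = 0.0518). Genes for piRNAs, which silence transposons in the germ line, were near 24 peaks (1.69% against 1.90%, exact adjusted p = 0.861), and lincRNA, rRNA and pseudogene starts did not pass either. Against random positions piRNA genes (odds ratio 0.354, exact adjusted p = 2.22e-08) and pseudogenes (odds ratio 0.446, exact adjusted p = 0.0032) passed below background. So did piRNA genes without replicate 2 (odds ratio 0.607, exact adjusted p = 0.0428) and pseudogenes with a 1000 bp window (odds ratio 0.606, exact adjusted p = 0.0258). Reads that lie wholly within a repeated tRNA sequence cannot be assigned to a single copy, and 472 of the 612 tRNA genes have a sequence that occurs more than once in the genome.

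**Figure D3:**
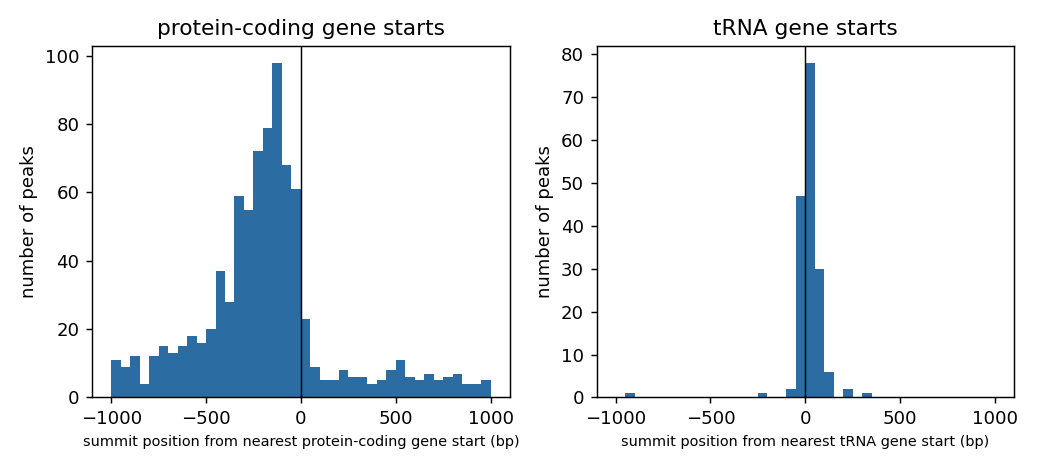
Number of thresholded peaks (y axis) by position of the summit from the nearest protein-coding (left) or tRNA (right) gene start (x axis, bp, negative values upstream, 50 bp bins). Protein-coding summits gather upstream, with the fullest bin holding 98 peaks, and tRNA summits gather around the start, with 78 peaks in the first 50 bp after it.

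In total 825 of 19973 protein-coding genes (4.13%) had a thresholded summit within 500 bp of the start, and 13 of the 41 gene lists differed from other genes, 8 with more bound genes and 5 with fewer. A peak could count for several genes, since 184 of the 657 promoter peaks lay within 500 bp of more than 1 start. Of 81 ribosomal protein genes 21 had a peak (25.9%, odds ratio 8.31, exact adjusted p = 1.8e-10), among them rps-24 (signal 473), rps-26 (389) and rpl-15 (327). The summits of these 3 genes lay 346, 405 and 365 bp before the start. Without summits near tRNA, snoRNA, snRNA or microRNA genes the odds ratio was 6.36 (exact adjusted p = 1.07e-06). The rps-26 peak is also the peak of the snoRNA gene F39B2.14. Of 42 translation factor genes 11 had one (26.2%, odds ratio 8.33, exact adjusted p = 7.58e-06), led by eif-3.B (signal 518) and eif-3.E (444), subunits of an initiation factor. Of 59 splicing genes 13 had one (22.03%, odds ratio 6.65, exact adjusted p = 7.58e-06), among them mog-3 (signal 513) and snr-1 (429), which encodes an Sm protein. Transfer RNA synthetase genes did not pass (4 of 32, exact adjusted p = 0.106), except among the 708 peaks of highest signal (exact adjusted p = 0.0347). In another setting each peak counted for its nearest start only, with no limit on distance. The odds ratios there were 2.77 for ribosomal proteins (exact adjusted p = 0.0169), 3.403 for translation factors (exact adjusted p = 0.0258) and 2.95 for splicing (exact adjusted p = 0.0256). That setting also adds distant peaks, so these falls do not measure the effect of shared starts. Among genes with no other start within 500 bp the odds ratios were 8.18, 12.1 and 4.80 in the same order (exact adjusted p = 4.02e-06, 2.58e-05 and 0.0243). With a 250 bp window they were 3.68 for ribosomal proteins (exact adjusted p = 0.0225), 5.25 for splicing (exact adjusted p = 0.0059) and 4.08 for translation factors, which did not pass there (exact adjusted p = 0.0783).

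Of 43 genes of the synMuv and chromatin list 10 had a peak (23.3%, odds ratio 7.11, exact adjusted p = 5.33e-05), among them lin-35, mys-1 (an acetyltransferase, signal 375), set-2 (a histone methyltransferase, 367) and rbbp-5 (256). This call ended when each peak counted for its nearest start only (odds ratio 1.90, exact adjusted p = 0.336) and with a 250 bp window (3.98, exact adjusted p = 0.0783). It stayed for genes with no other start within 500 bp (5.28, exact adjusted p = 0.0189). Starts more than 500 bp apart can still share a peak that lies between them. That setting therefore cannot tell how far shared starts account for the loss by nearest start. Each count below is again of genes with a peak. Of 59 cell cycle genes 11 had one (18.6%, odds ratio 5.38, exact adjusted p = 0.000149), including lin-35, which both lists hold, spd-5 (a centrosome protein, signal 571) and the kinetochore genes bub-1 (272) and knl-1 (183). The odds ratio of the cell cycle list was 2.95 by nearest start only (exact adjusted p = 0.0256). The call ended among genes with some pooled region at their start (2.69, exact adjusted p = 0.0522). The bub-1 peak is also the peak of lin-61, a member of the chromatin list, and the spd-5 peak is also that of the nuclear pore gene npp-6.

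Of 14 chaperonin and prefoldin genes 5 had a peak (35.7%, 95% interval 12.8 to 64.9, exact adjusted p = 0.000714), led by pfd-5 (signal 376), pfd-4 (299) and cct-7 (234). For genes of this list with no other start within 500 bp the odds ratio was 15.8 (exact adjusted p = 0.0125). The odds ratio of this list was 13.0, and it fell to 3.93 by nearest start only (exact adjusted p = 0.169) and 6.45 with a 250 bp window (exact adjusted p = 0.13), where the call ended. Of 18 genes of the unfolded protein response 6 had one (33.3%, 13.3 to 59.0, exact adjusted p = 0.000269): pdi-6, enpl-1, atf-6, hsp-3, cnx-1 and xbp-1. Among the 708 peaks of highest signal the odds ratio of this list fell from 11.7 to 2.26 and the call ended (exact adjusted p = 0.805). The heat shock list did not pass (2 of 22, exact adjusted p = 0.449), except with a 1000 bp window (odds ratio 4.97, exact adjusted p = 0.019). The hsp-3 region ranked 509 in replicate 2 and 17360 in replicate 1, so its peak rests on replicate 2. Of 57 oxidative phosphorylation genes 7 had one (12.3%, odds ratio 3.27, exact adjusted p = 0.03), led by atp-5 (signal 376). This call ended by nearest start only (odds ratio 1.70, exact adjusted p = 0.397), with a 250 bp window (2.15, exact adjusted p = 0.396) and among the 708 peaks of highest signal (2.14, exact adjusted p = 0.507). It also ended for starts with no other within 500 bp (2.78, exact adjusted p = 0.239), without replicate 1 (2.74, exact adjusted p = 0.0939) and without replicate 2 (2.86, exact adjusted p = 0.0785). The cox-5A region in this list ranked 438 in replicate 1 and 6771 in replicate 2. In the same order, the mev-1 region ranked 3742 and 968, and that of another member 783 and 4574. Other lists past the threshold hold such peaks too, such as a cell cycle gene with ranks of 6157 and 936.

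Several large gene families were bound less often than other genes. Chemoreceptor genes had peaks at 5 of 1309 (0.382%, odds ratio 0.0834, exact adjusted p = 1.01e-16, and 0.0498 without replicate 1), F-box and MATH genes at 2 of 412 (0.485%, exact adjusted p = 5.33e-05) and innate immunity genes at 1 of 312, clec-126 (0.321%, exact adjusted p = 0.000215). Nuclear hormone receptor genes had peaks at 3 of 269, nhr-142, nhr-1 and nhr-49 (1.12%, odds ratio 0.259, exact adjusted p = 0.0293), and detoxification genes at 2 of 215, dhs-1 and gst-27 (0.93%, odds ratio 0.216, exact adjusted p = 0.0442). The receptor call ended by nearest start only (odds ratio 0.553, exact adjusted p = 0.169) and among the 708 peaks of highest signal (0.141, exact adjusted p = 0.0628). It ended with any transcript start (0.397, exact adjusted p = 0.115). It also ended without replicate 1 (0.347, exact adjusted p = 0.0939) and without replicate 2 (0.549, exact adjusted p = 0.381). The detoxification call ended among the 708 peaks of highest signal (0.357, exact adjusted p = 0.507) and with any transcript start (0.398, exact adjusted p = 0.171). It also ended without replicate 1 (0.216, exact adjusted p = 0.0524) and without replicate 2 (0.225, exact adjusted p = 0.0501). Both ended for starts with no other within 500 bp (0.368 for receptors and 0.318 for detoxification, exact adjusted p = 0.239 for each). Lists of tissue markers did not pass the threshold: 0 of 29 intestine genes, 0 of 18 pharynx genes, 0 of 11 hypodermis regulators, 2 of 50 neuronal function genes, 1 of 43 neuronal regulators and 1 of 48 germline and maternal genes had a peak. These lists hold too few genes to pass below other genes even with no bound gene, and the upper 95% bounds for the first 3 are 11.9%, 18.5% and 28.5%. Body wall muscle genes had 5 of 43, among them unc-60 and unc-112, which did not pass after adjustment (exact adjusted p = 0.0855). When only genes with some pooled region at their start were compared, which leaves out only genes without a thresholded peak, 4 lists stayed above other genes (odds ratio 3.02 for ribosomal proteins, 3.08 for splicing, 4.44 for translation factors, 3.81 for synMuv and chromatin) and 3 below (0.31 for chemoreceptors, 0.158 for F-box and MATH, 0.122 for innate immunity). The other 6 calls ended there. The odds ratio was 4.098 for the unfolded protein response and 4.88 for chaperonins (exact adjusted p = 0.0522 for each). It was 1.49 for oxidative phosphorylation (exact adjusted p = 0.714). It was 0.316 for nuclear hormone receptors (exact adjusted p = 0.141) and 0.33 for detoxification (exact adjusted p = 0.481). The nuclear pore list (4 of 26, odds ratio 4.24, exact adjusted p = 0.0613) and the proteasome list (3 of 33, odds ratio 2.33, exact adjusted p = 0.316) did not pass, but both did with a 1000 bp window (exact adjusted p = 0.0324 and 0.0251). The nuclear pore list also did without summits near small RNA genes (exact adjusted p = 0.0497).

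**Figure D4:**
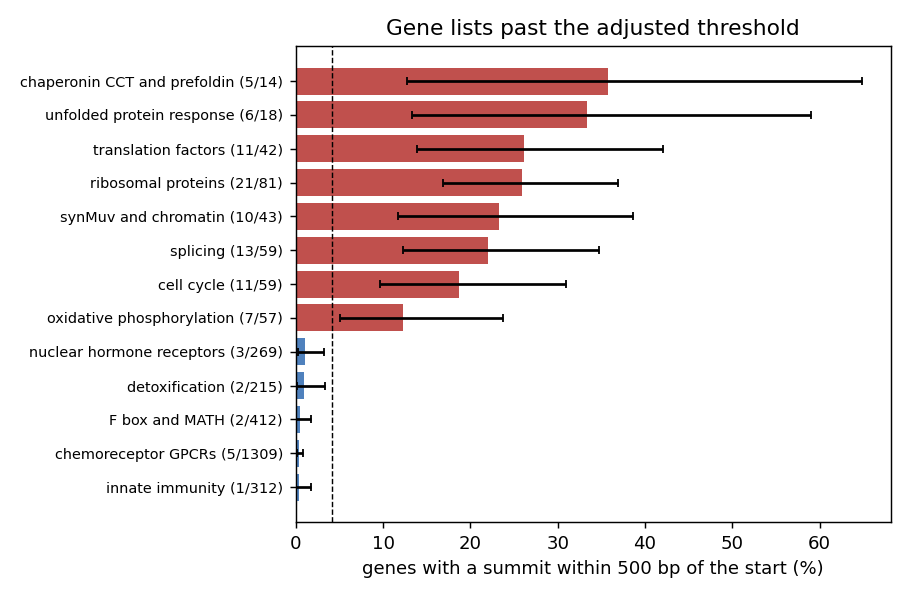
Share of genes with a thresholded summit within 500 bp of the start (x axis, percent) for the 13 gene lists past the adjusted threshold (y axis, bound and total genes in parentheses), with 95% Clopper-Pearson intervals as error bars and a dashed line at 4.13%, the share of all protein-coding genes. Red bars are 8 lists above other genes and blue bars 5 lists below.

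The peaks were spread over all 6 chromosomes, with 260 on I, 232 on II, 259 on III, 209 on IV, 193 on V and 263 on X. Chromosome V held 13.6% of peaks (11.9 to 15.5) against 16.8% of background regions (odds ratio 0.781, exact adjusted p = 0.0088), a call that ended among the 708 peaks of highest signal (14.8%, exact adjusted p = 0.508) and without summits near tRNA genes (14.01%, exact adjusted p = 0.0502). It stayed without replicate 1 (odds ratio 0.744, exact adjusted p = 0.000843) and without replicate 2 (0.771, exact adjusted p = 0.00425). Against random positions V held fewer peaks too (13.6% against 21.2%, odds ratio 0.587, exact adjusted p = 1.58e-11). Chromosome X, which differs from the autosomes in gene content and dosage, held 18.6% (16.6 to 20.7) against 16.4%, which did not pass (odds ratio 1.16, exact adjusted p = 0.109). It passed in the replicate 2 list alone (19.1%, exact adjusted p = 0.0221). Chromosome III did not pass (18.3%, odds ratio 1.105, exact adjusted p = 0.314). It did in the replicate 1 list alone (18.9%, odds ratio 1.19, exact adjusted p = 0.0413) and against random positions (odds ratio 1.39, exact adjusted p = 3.46e-05), where chromosome I passed too (odds ratio 1.28, exact adjusted p = 0.00196). Without summits within 500 bp of a tRNA gene start, X held 15.4% of peaks against 16.2% of background regions (exact adjusted p = 0.649).

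Summits were rich in G and C. Mean GC content in 101 bp windows was 50.2% (SD 7.94 across 1416 peaks) against 43.7% (SD 9.11) in background regions, a difference of 6.51 percentage points (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give), and 36.2% in the flanks. With windows of 100 bp to either side of the summit the difference from background was smaller, 3.95 percentage points. Against the flanks, 1572 7-mers were enriched at summits and 1138 depleted. CTAGGCC was in 8.55% of summit windows and 0.388% of flanks (odds ratio 24.0, exact adjusted p = 1.24e-42, and 14.2 without replicate 2), CTCTCTC in 11.1% and 1.62%, CACGGCC in 6.92% and 0.282%, and GAGACGC in 8.12% and 0.777%. Against GC-matched background the odds ratio went from 7.55 to 2.55 for CTCTCTC, 26.2 to 6.12 for CACGGCC and 11.3 to 2.47 for GAGACGC. The most depleted was AAAAATT, in 5.65% of summit windows and 24.0% of flanks. The number enriched was 1017 against all background regions, 381 against an unmatched sample of 1416 of them and 261 against 1416 of matched GC content, and all 20 of the most enriched 7-mers passed there. Many of the 20 overlap in sequence, such as CTAGGCC and TAGGCCA, and they were picked in the same summit windows. They are therefore not separate results. Among the 271 peaks over 1000 bp from any gene start, 12 of those 20 passed, and CTAGGCC did not (odds ratio 2.69, exact adjusted p = 0.691).

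The build made little difference. The thresholded list held 1414 peaks on ce10 and 1416 on ce11, and signal at the same rank differed by at most 7.72%.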

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

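Alternatives that matched on GC content, stratified by it, left out masked bases or small RNA genes, used any transcript start or sampled fewer windows were chosen after seeing the data. Taking the 1416 highest-signal pooled regions gives the thresholded list itself, so it tested nothing. The ce10 alternative for the tagged locus was not run, because no ce10 annotation was used here. No paired analysis was possible because there is 1 group. Depth is unknown, so its effect was not tested, and the causes below were not tested unless a smaller set is named.

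The peak count, the replicate overlap (59.6% to 81.5%), the promoter share (30.2% to 59.5%), the number of classes and biotypes past the threshold and the GC difference kept their direction and side. Without a replicate, X held 17.8% to 19.1% of peaks, and it passed in the replicate 2 list. X held 15.4% without summits near tRNA genes, below background. Lists above other genes numbered 8, and 12 with a 1000 bp window and 4 with a 250 bp window or only genes with a pooled region. Lists below numbered 5, and 3 with the stronger peaks, genes with a pooled region, isolated starts, GC strata or any transcript start, and 3 to 3 without a replicate. Of the 13 lists, 5 passed in every setting run: ribosomal proteins, splicing, chemoreceptors, F-box and MATH, and innate immunity. Enriched 7-mers numbered 1572, and 779 with the stronger peaks, 715 for 6-mers (fewer exist), 979 within 25 bp, 1017 against background regions, 176 in the 271 peaks over 1000 bp from any gene start, 261 GC-matched (381 unmatched at that size) and 319 without masked bases (351 for random windows of that number).

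Directions that turned did so mostly for values not past the threshold. The intergenic share was 27.3% with a 250 bp window and passed. With random positions 5′ UTRs (0.918%), downstream sequence (3.81%), II (16.4%) and IV (14.8%) changed side of the background, as did downstream sequence with 1000 bp (3.04%), piRNA genes with 1000 bp (3.11%) and I in the stronger peaks (18.2%). The lincRNA share equalled the background when GC-matched (0.282%). Leaving out a replicate gave 0.847% to 1.06% for 5′ UTRs, 17.8% to 17.9% for I, 16.1% to 17.2% for II and 14.1% to 15.4% for IV, with the side changed without replicate 2. Cuticle collagens, with a main odds ratio of 0.681, had 1.95 with 1000 bp and 1.87 by nearest start, both past the threshold, and 0.822 to 1.16 without a replicate. Odds ratios also turned above 1 for hypodermis regulators (3.20 nearest start, 0 to 2.42 without a replicate), pharynx (1.24 any transcript start, 0 to 1.43 without a replicate), neuronal function (2.35 nearest start, 1.46 isolated starts, 1.06 without small RNA genes, 0.472 to 1.01 without a replicate) and germline genes (0.493 to 1.05 without a replicate). Of the values for single classes, chromosomes, biotypes, lists and the 10 most enriched 7-mers, 483 kept direction and side, 40 lost and 19 gained the threshold in the same direction, and the 25 others are the turned or equal values above, of which 3 newly passed. These counts leave out the setting that gives the thresholded list itself and 15 lists that passed in no setting and hold no tissue markers. The choice of lists was made after the first tables were read.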

Other observations

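The tests of explanations below were chosen after the patterns were seen, as well as the mean GC content and masked share of summits, but what each should show was written before its outcome was seen. The same-size samples of windows were added after the GC-matched and unmasked results. No biological explanation was tested, since the design has 1 group.

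The tRNA genes with peaks were spread over isotypes and chromosomes. X carries 276 of the 612 annotated tRNA genes (45.1%), and 29.7% of these had a peak against 30.4% of the 336 on autosomes (Fisher exact p = 0.929). None of the 20 isotypes with at least 10 genes differed from the other tRNA genes after adjustment (exact adjusted p = 1 for each, 0 isotypes under an unadjusted p of 0.05), with shares from 16.7% for tRNA-Trp to 41.5% for tRNA-Glu. The tRNA peak of highest signal (512, rank 49) lay at C04A11.t1, a leucine tRNA gene on X. Other small RNA genes with strong peaks were the snoRNA genes T06C12.16 (signal 517) and F59C6.15 (516), and the microRNA genes mir-51 (375) and mir-52 (255). Among snRNA-class genes, sls-2.1, sls-2.4 and sls-2.8, which encode spliced leader RNAs used in trans-splicing of operon transcripts, had peaks with signals of 257, 210 and 188. The sls-2.8 peak ranked 284 in replicate 2 and 1027 in replicate 1. Peaks near tRNA genes had a median signal of 161, those near protein-coding starts 154 and those near neither 122.

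Peaks near tRNA genes were weighed against 3 technical explanations. Among summits over 500 bp from any protein-coding start, the tRNA odds ratio was 22.5 with a lower 95% bound of 17.7, which argues against closeness to promoters as the whole cause. Against GC-matched background windows the ratio was 13.4 with a lower bound of 7.7, which argues against GC content. Of 140 tRNA genes whose sequence occurs once, 20.7% had a peak against 4.13% of protein-coding genes (odds ratio 6.06, lower bound 3.86). This cannot settle how far reads shared between identical copies account for the pattern. A peak within 500 bp can belong to a neighbouring tRNA gene with a repeated sequence. For example, the tRNA genes M02F4.t1 and M02F4.t2, of different isotypes, share 1 peak. Of the 472 tRNA genes whose sequence occurs more than once, 32.8% had a peak, more often than those that occur once (odds ratio 1.87, 1.17 to 3.05, Fisher exact p = 0.00625, a test chosen after both shares were seen), so shared reads may account for part of the tRNA peaks. Recovery of open or highly transcribed chromatin without contact by the tagged protein stays open, because no untagged library was analysed here.

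For the 7-mers, 14.1% of the 1572 enriched against flanks stayed enriched against GC-matched background, and 23.7% did against an unmatched background sample of the same size, so most of the fall came with the change from flanks to background regions and the smaller number of windows, and GC content may account for part of the rest. In windows with no soft-masked base 19.8% stayed, and 22.1% did in as many windows taken at random. Masked bases made up 19.2% of summit windows, 33.6% of flanks, 23.02% of background windows and 35.7% of the genome, so masked sequence as a whole was not more common at summits, but single repeat families were not tested. The share in flanks was computed after these results. Neither test settles how far GC content or repeats account for the whole set. The 7-mer test was not repeated without summits near tRNA or other small RNA genes. How many of the enriched 7-mers rest on those summits was therefore not measured. All 20 of the most enriched 7-mers passed against GC-matched background, CTAGGCC with an odds ratio of 5.42 (exact adjusted p = 1.28e-13), and 18 of the 20 passed in unmasked windows against 20 in as many windows taken at random. The 20 overlap in sequence and were picked in the same summit windows, so their passing together is weak evidence. CTAGGCC was in 3.13% of unmasked summit windows (exact adjusted p = 0.00167) and in 8.35% of those taken at random, so it was rarer where no base was masked.

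For the gene lists, 10 of the 13 calls stayed after stratifying genes by GC content at the start, and 12 stayed without summits near tRNA, snoRNA, snRNA or microRNA genes, which argues against either as the cause of the lists as a whole. The calls lost under GC strata kept similar odds ratios: oxidative phosphorylation went from 3.27 (1.25 to 7.27) to 2.95 (1.32 to 6.61), nuclear hormone receptors from 0.259 (0.053 to 0.768) to 0.253 (0.0809 to 0.791) and detoxification from 0.216 (0.026 to 0.793) to 0.253 (0.0626 to 1.03), with 95% intervals. These sat close to the threshold before (adjusted p of 0.03, 0.0293 and 0.0442) and missed it after (0.0554, 0.0557 and 0.161), so GC content is not excluded for them. Without small RNA genes, oxidative phosphorylation had an odds ratio of 3.002 (1.05 to 7.03, exact adjusted p = 0.0599), so small RNA genes are not excluded for that list. Recovery of open chromatin at active promoters was not tested for the lists and stays open.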
